A study of Urocitellus parryii with 3 samples.

How the data were processed

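Liver RNA of arctic ground squirrels was profiled on microarrays that carry probes for mouse miRNAs. Per the labels' protocols, total RNA was extracted with TRIzol, its quality was assessed on a Bioanalyzer, and equal amounts from animals of the same stage were mixed into 1 pool per stage. The number of animals in a pool is not given in the sources used here. Each pool was labelled with Cy3 and hybridised to 1 array, which gives 3 arrays in all. All of them lay on the same slide, so no slide batch separates them, but stage, pool and array position cannot be told apart.

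Per the submitters' processing notes and the file headers, the arrays were read with Agilent Feature Extraction 9.5.3.1. Per the file headers, the deposited intensity of a spot is its signal after a fitted spatial background trend was subtracted. Local background subtraction and multiplicative detrending were switched off, and no step made the arrays comparable with each other. The deposited detection and outlier flags are other values made by the same program, per the file headers. The authors' deposited series table held the same intensity as the scanner files at every one of 12493 spots on each array, on a linear, uncentred scale. Its median was 1.05 for early arousal, 1.15 for late torpor and 1.13 for post-reproduction.

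Each array had 11540 spots for 577 miRNA entries and 953 control spots. Of the entries, 567 were mouse miRNAs and 10 were viral miRNAs, which served as background. An entry had 1 to 4 probes and each probe 5 to 20 spots. Control spots were left out, as were spots flagged as outliers: 398 on the early arousal array, 280 on the late torpor array and 317 on the post-reproduction array. No spot for a miRNA entry was saturated. A spot at or below 0 was set to the lowest intensity of a spot well above background on its array (10.1 for early arousal, 8.49 for late torpor and 10.7 for post-reproduction), a rule fixed before the data were examined. This applied to 39.8%, 38.2% and 37.5% of the kept spots in that order, and to 0 spots of detected probes, so it did not enter the values of measured miRNAs. It placed such spots above spots with a weak positive intensity. The log2 intensity was averaged over the spots of a probe. A probe counted as detected where more than 50% of its kept spots were marked well above background. Fewer than 20% of probes were detected on any array, so each array was scaled by subtracting its 75th percentile over the 250 probes detected on all 3 arrays. That percentile was 350.4 intensity units for early arousal, 349 for late torpor and 398 for post-reproduction. A miRNA's value was the mean over its probes detected on all 3 arrays, and a miRNA with such a probe is called measured. Of the mouse entries, 135 were measured.

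No test across arrays was made, since 1 array per stage gives no spread between animals, pools or arrays. A difference is a difference of log2 values, with a standard error (SE) from the spots of each probe. That SE covers spot spread only, and so do the 95% intervals of folds. The median SE was 0.03 in each comparison. Where a miRNA had at least 2 measured probes (105 miRNAs), the range of the probes' log2 differences had a median of 0.063 to 0.073 and reached 0.61 at most. A miRNA passed the rule of size where its log2 difference was at least 1 (2-fold), more than 2 times its SE and of the same sign in each of its measured probes. A miRNA detected on 1 of the 2 arrays compared has a bound. Its brightest probe was set against the higher of that probe's own value on the dim array and the lowest signal of any spot well above background there. That floor was 8.49 to 10.7 intensity units. It was chosen after the data were examined, because on the late torpor array 1 detected probe had a mean of only 2.39. That value is a mean of logs turned back to intensity. The mean deposited intensity of that probe, of miR-466h, was 14.2. A floor at the lowest mean of a detected probe was kept as an alternative. Bounds move with the scaling as differences do, and they were also computed under each scaling that shifts whole arrays, but not after quantile normalization.

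Lists of miRNAs were fixed before the data were examined, as were the groups, the scaling, the rule of size and all but 2 alternatives. There were 21 lists. They covered hepatocyte, red blood cell (erythroid), leukocyte, endothelial, mesenchymal, muscle, neural and pancreatic miRNAs. They also covered the let-7, miR-200, miR-29, miR-30, miR-15 and miR-23 families, the miR-17 cluster with its paralogs, and the imprinted Dlk1-Dio3 cluster. Further lists held miRNAs of lipid metabolism, miRNAs of stress responses, GC-rich entries, star strands and viral entries. The GC-rich list holds entries that are often bright on such arrays because of their sequence or a match to other RNA. A list's median difference was placed among 10000 random lists of the same size, matched on mean intensity in 10 bins. This describes these arrays and is not a test. A list with fewer than 3 measured members has values only. With 15 lists in 3 comparisons there were 45 such placements, of which 2.25 would lie outside the middle 95% by chance if the members of a list were unrelated. Members of a family or cluster may vary together, and signal shared between their probes was not checked. More placements could therefore lie outside by chance.

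The miRNAs named were chosen by rule. Per comparison these were the 10 highest and 10 lowest past the rule of size, up to 5 bounds per direction of at least 2-fold, and each list's highest, lowest and brightest member. miR-122, miR-21, miR-200a, miR-210, miR-211, miR-378, miR-451, miR-486, miR-34a and miR-155 were named in any case, with the 5 brightest miRNAs of each array. Names are those of the array's design. Coordinates are those the files give for the mouse targets of the probes (build mm9), since no ground squirrel genome was used here. Probe sequences and their match to ground squirrel miRNAs were not analysed here, so levels of different miRNAs are not compared as amounts.

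The alternatives were other scalings (the 75th percentile over all probes, the median over detected probes, none, and quantile normalization), a normexp background correction with an offset of 50, the brightest probe, the deposited total intensity per miRNA, a stricter detection call, the brighter miRNAs alone, other rules of size and the deposited series table. The substituted spots entered the all-probe scaling and quantile normalization. On the early arousal and late torpor arrays the percentile over all probes was the substituted value itself. An unsubstituted all-probe scaling was therefore added after the data were examined. It took the percentile of the probes' mean intensities as deposited, which was 3.32, 3.83 and 3.33 in the order above. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used, with limma 3.58.1 in R 4.3.3 for normexp and matplotlib 3.10.9 for plots. The rule of size was tested on 50 simulated sets of late torpor and post-reproduction arrays with the 135 measured miRNAs and real spot noise. It recovered 99.4% of 2.5-fold changes, 100% of 4-fold changes, 0% of 1.5-fold changes and 0% of unchanged miRNAs. The simulated arrays held no spread between pools or arrays. With spot noise this small the size required nearly fixes these shares, so they are not error rates for real pools.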

Results

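The liver of the arctic ground squirrel (Urocitellus parryii), a hibernator, was compared between 3 stages of the animal's year: late torpor, when body temperature and metabolism are low, early arousal, when the animal rewarms, and post-reproduction, outside the hibernation season. Each stage was 1 pool of total RNA on 1 array, so no difference below has a replicate check, and the number of arrays limits the precision. On the early arousal array 152 of the 567 mouse miRNAs were detected, on the late torpor array 158 and on the post-reproduction array 143. The median negative control spot lay at 1.36, 1.69 and 1.21 intensity units in the same order, over 672 spots per array, and the SD of these spots was 3.61, 4.13 and 11.6.

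miR-122, the main miRNA of hepatocytes, was the brightest entry on every array, with 33094 intensity units in early arousal, 37937 in late torpor and 34109 in post-reproduction. miR-720, let-7a and miR-22 were among the 5 brightest on each array. let-7f completed the 5 in early arousal and post-reproduction, and miR-451, a red blood cell miRNA, did so in late torpor. Muscle and pancreatic miRNAs had no measured member. The neural list had 1 measured member (miR-128) of 7, and the Dlk1-Dio3 list, drawn from a cluster that is quiet in adult liver, had 1 (miR-127) of 32. By the position of its target, miR-494 of the GC-rich list lies among the members of that cluster too, as does miR-540-3p.

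The first comparison asked how the liver's miRNAs in late torpor differ from those outside hibernation. The 3 red blood cell miRNAs were the ones past the rule of size, all higher in late torpor. miR-144 was 2.79-fold higher (95% interval from spots 2.68 to 2.90), miR-486 was 2.48-fold higher (2.38 to 2.58) and miR-451 was 2.36-fold higher (2.31 to 2.42). Each rested on 2 probes with 18 to 20 spots per array. With normexp miR-144 (0.75) and miR-486 (0.80) fell short of the rule, as did miR-451 after quantile normalization (0.83), and miR-451 (0.85) and miR-486 (0.92) with the unsubstituted all-probe scaling. miR-144 and miR-451 are made from 1 cluster. Its targets in the files lie on mouse chromosome 11, at 77886549 to 77886568 for miR-144 and at 77886688 to 77886709 for miR-451 (mm9). The target of miR-486 lies on chromosome 8, at 24253067 to 24253080. No measured miRNA was lower past the rule. The median difference of the erythroid list, 1.31, lay at the 99.7th percentile of matched random lists.

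The leukocyte list lay on the same side in 5 of its 6 measured members, with a median of 0.37 (87.5th percentile) and none past the rule, but 3 of the 6 were lower and the median was -0.018 with the unsubstituted all-probe scaling. miR-223, a myeloid miRNA, had a difference of 0.67 ± 0.02 (SE from spots), and miR-146a was the exception with -0.27 ± 0.03. All 8 measured miRNAs of the miR-17 list were higher in late torpor, from 0.33 for miR-92a to 0.57 for miR-19a, with a median of 0.44 (95.3rd percentile), but miR-20b and miR-92a were lower with the unsubstituted all-probe scaling. The list came to lie outside the middle 95% with the brightest probe (0.47) and with strict detection (0.20), as did the miR-15 list with strict detection (0.35). All 6 of the miR-15 list were higher too, with a median of 0.37 and miR-15b at 0.88 ± 0.02, but miR-322 was lower with all probes in the scaling, miR-195, miR-322 and miR-497 without scaling and with the unsubstituted all-probe scaling, and miR-195 and miR-497 after quantile normalization. The GC-rich list stood outside the middle 95% with a median of 0.70 (99.5th percentile): miR-494, miR-1224 and miR-709 were higher by 0.83, 0.70 and 0.70, and miR-720 was at -0.16. In the brighter miRNAs alone the list came inside, at the 96.6th percentile. The miR-200 family, found in bile duct and other epithelia, had 2 measured members. miR-200b was at -0.89 ± 0.06, and it passed the rule with the total intensity (-1.13) and strict detection (-1.13) as well as under other scalings, and miR-200a at -0.62 ± 0.07.

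The 7 measured hepatocyte miRNAs were higher, by 0.027 for miR-194 to 0.47 for miR-193, but miR-194 was lower under each other scaling and miR-192 was lower without scaling and after quantile normalization. With the unsubstituted all-probe scaling 6 of the 7 were lower. miR-122 was at 0.34 ± 0.03, which also turned below 0 there. Their median of 0.30 lay at the 83.8th percentile. In the lipid list, miR-378, encoded in an intron of the gene of a mitochondrial coactivator (Ppargc1b), was the lowest at -0.77 ± 0.03 (past the rule with strict detection), while its star strand miR-378* was the highest at 0.28. In the stress list, miR-21 was at 0.37 ± 0.01 (both of these below 0 with the unsubstituted all-probe scaling) and miR-34a, a target of p53, at 0.084 ± 0.03, a sign that turned under each other scaling. let-7 members went both ways, 5 higher and 4 lower, with a median of 0.018 (9.1th percentile) that was below 0 under each other scaling. The miR-29 list had a median of 0.25 (3 of 3 higher, miR-29b lower without scaling and after quantile normalization, 3 of 3 lower with the unsubstituted all-probe scaling), the miR-30 list 0.18 (4 of 5 higher, below 0 without scaling, after quantile normalization and with the unsubstituted all-probe scaling) and the miR-23 list -0.067 (3 of 5 lower, and 5 of 5 under each other scaling). The medians of the lipid, stress, endothelial and star lists were 0.081, 0.11, 0.024 and 0.022, each below 0 under each other scaling, and that of the mesenchymal list was -0.016. miR-128 of the neural list was at 0.59 and miR-127 of the Dlk1-Dio3 list at -0.15. Endothelial miRNAs went both ways, from -0.42 for miR-222 to 0.35 for miR-126-3p (4 of 4 lower with the unsubstituted all-probe scaling), and mesenchymal ones went from -0.16 for miR-214 to 0.079 for miR-143 (5 of 5 lower under each other scaling). Among star strands, miR-31* was the highest at 0.86 and miR-483* the lowest at -0.35. miR-133b was at least 2.27-fold higher in late torpor and miR-29b* at least 2.06-fold higher, both not well above background in post-reproduction. These bounds were as low as 1.73-fold and 1.57-fold under the other scalings that shift whole arrays. In late torpor the brightest probes of miR-133b and miR-29b* had 21.2 and 19.3 intensity units. That is below the 26.3 of mghv-miR-M1-2, a viral background entry, on the same array. miR-155 and miR-210 were not detected on any array. miR-211 was detected in late torpor and post-reproduction, and not in early arousal, so it was not measured and is not in the counts above. Its brightest probe was lower in late torpor than in post-reproduction, with scaled log2 values of -4.99 and -3.36. On the late torpor array that probe was dimmer than mghv-miR-M1-2.

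The median of all 135 measured miRNAs was 0.13 in this comparison, and it was 0.0072 with the array scaled on all probes, 0.021 with the median, -0.059 without scaling and -0.020 after quantile normalization. Under the first 3 of these, miR-200b was lower past the rule beside 3 miRNAs that were higher. After quantile normalization 2 were higher and 0 lower. The unsubstituted all-probe scaling, chosen after the data were examined, moved the median to -0.26 and gave 1 higher and 6 lower, with miR-200b (-1.28), miR-378 (-1.16) and miR-200a (-1.01) among the lower ones.

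**Figure D1:**
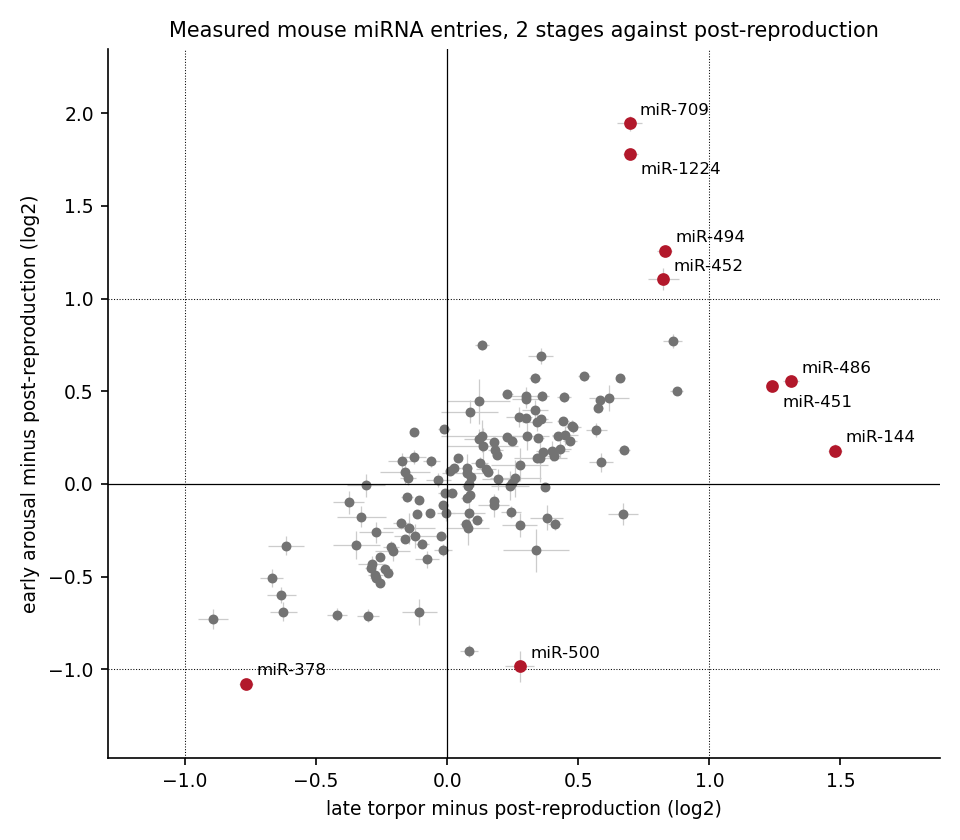
Log2 difference of each of the 135 measured mouse miRNAs from post-reproduction, in late torpor (horizontal axis) and early arousal (vertical axis), with bars for the SE from spots and dotted lines at a log2 difference of 1 in size. Red points passed the rule of size in at least 1 comparison: miR-144, miR-486 and miR-451 lie to the right (1.48, 1.31 and 1.24), and miR-709 and miR-1224 lie at the top (1.94 and 1.78).

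The second comparison asked how early arousal differs from post-reproduction. The miRNAs past the rule were 4 higher and 1 lower. miR-709 was 3.85-fold higher (95% interval from spots 3.63 to 4.07), miR-1224 was 3.44-fold higher (3.32 to 3.56) and miR-494 was 2.39-fold higher (2.30 to 2.49). These belong to the list of GC-rich entries, whose median of 1.52 lay above nearly all random lists (100th percentile after rounding), with miR-720, the brightest member, at -0.30 ± 0.01. Of the 11 entries of that list that were not measured, 8 were brighter in early arousal, and the median difference was 1.24 intensity units. Of these 11, 4 were detected in early arousal and 0 in post-reproduction. Of the 7 detected on no array, 4 were brighter, with a median difference of 0.204. miR-452 was 2.15-fold higher (1.98 to 2.33), but it fell short of the rule with all probes in the scaling (0.73), with the unsubstituted all-probe scaling (0.92), without scaling (0.92), with strict detection (0.84) and with normexp (0.46). miR-494 fell short with all probes (0.89), strict detection (0.99) and normexp (0.78). miR-709 rested on 1 probe with 10 spots per array, miR-1224 on 3 probes with 15 spots and the others on 2 probes with 18 to 20 spots. miR-378 was 2.11-fold lower, with a log2 difference of -1.08 ± 0.02, and at -0.52 with normexp it fell short of the rule. Its target lies on mouse chromosome 18, at 61557492 to 61557505, and that of miR-709 on chromosome 8, at 86610073 to 86610084.

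All 9 measured members of the let-7 family, which marks differentiated cells, were lower in early arousal, also under the 5 other scalings. Whether their probes share signal was not checked, so the 9 need not be separate measurements. The members ranged from -0.51 for let-7b to -0.046 for let-7f, with a median of -0.21 (0.405th percentile) and none past the rule. The list came inside the middle 95% with normexp (-0.084, 4.47th percentile) and in the brighter miRNAs alone (-0.20). The miR-15 list was higher in all 6 members with a median of 0.45 (99.1st percentile), miR-15a being the highest at 0.57 ± 0.02, but miR-195 and miR-497 were lower with both all-probe scalings, without scaling and after quantile normalization. The miR-15 list came inside the middle 95% with the total intensity (0.34), strict detection (0.19) and the brighter miRNAs alone (0.48). The miR-17 list was higher in all 8 with a median of 0.39 (97.7th percentile), from 0.15 for miR-106b to 0.58 for miR-19b, but with all probes in the scaling 4 were lower, and miR-106b was lower without scaling, after quantile normalization and with the unsubstituted all-probe scaling. The list came inside the middle 95% after quantile normalization (0.31) and with the brightest probe (0.32). The red blood cell miRNAs were at 0.18 (miR-144, below 0 with both all-probe scalings and without scaling), 0.53 (miR-451) and 0.55 (miR-486), none past the rule. Their median lay at the 96.4th percentile. The leukocyte list had a median of -0.19 (0.044 with normexp), with miR-146a at -0.49 and miR-181a at 0.47.

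miR-34a was at -0.90 ± 0.03, short of the rule, but it passed with all probes in the scaling (-1.27), with the unsubstituted form (-1.08), without scaling (-1.08), with the total intensity (-1.03) and with strict detection (-1.16). miR-21 was at 0.17 ± 0.01. miR-200b was at -0.73 ± 0.05 (past the rule at -1.10 with all probes) and miR-200a at -0.33 ± 0.05. In the hepatocyte list, miR-365 was the highest at 0.48 and miR-148a the lowest at -0.014, and miR-122 was at 0.14 ± 0.03. The list's median of 0.16 was -0.22 with all probes in the scaling, -0.026 with the unsubstituted form and -0.029 without scaling, and it was also below 0 after quantile normalization. miR-222 was the lowest endothelial miRNA at -0.71 (past the rule at -1.08 with all probes) and miR-27a the lowest of the miR-23 list at -0.53. Among entries detected in early arousal and not well above background in post-reproduction, miR-671-3p was at least 3.33-fold higher, miR-483 at least 3.20-fold, miR-770-3p at least 2.81-fold and miR-188-5p at least 2.33-fold (1.80-fold with all probes in the scaling). For miR-671-3p and miR-770-3p the bound rested on 5 spots of 1 probe, the only 1 of 4 detected in early arousal. In the other direction, miR-211 was at least 3.37-fold and miR-190b at least 2.20-fold higher in post-reproduction. Their brightest probes had 38.8 and 25.3 intensity units there. In early arousal miR-671-3p, miR-483, miR-770-3p and miR-188-5p had 31.3, 30.1, 26.5 and 21.9. The viral background entry mghv-miR-M1-2 had 22.2 in early arousal and 26.5 in post-reproduction. Detection near this level does not show that a miRNA was present.

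The split of 4 higher and 1 lower depended on the scaling. It was 2 and 8 with all probes, 3 and 3 without scaling, 4 and 2 after quantile normalization and 3 and 3 with the unsubstituted all-probe scaling. The first of these moved the median of all measured miRNAs from 0.062 to -0.31, and miR-122, miR-144 and miR-21 were among those that changed sign under it and under the unsubstituted form, which moved the median to -0.12.

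**Figure D2:**
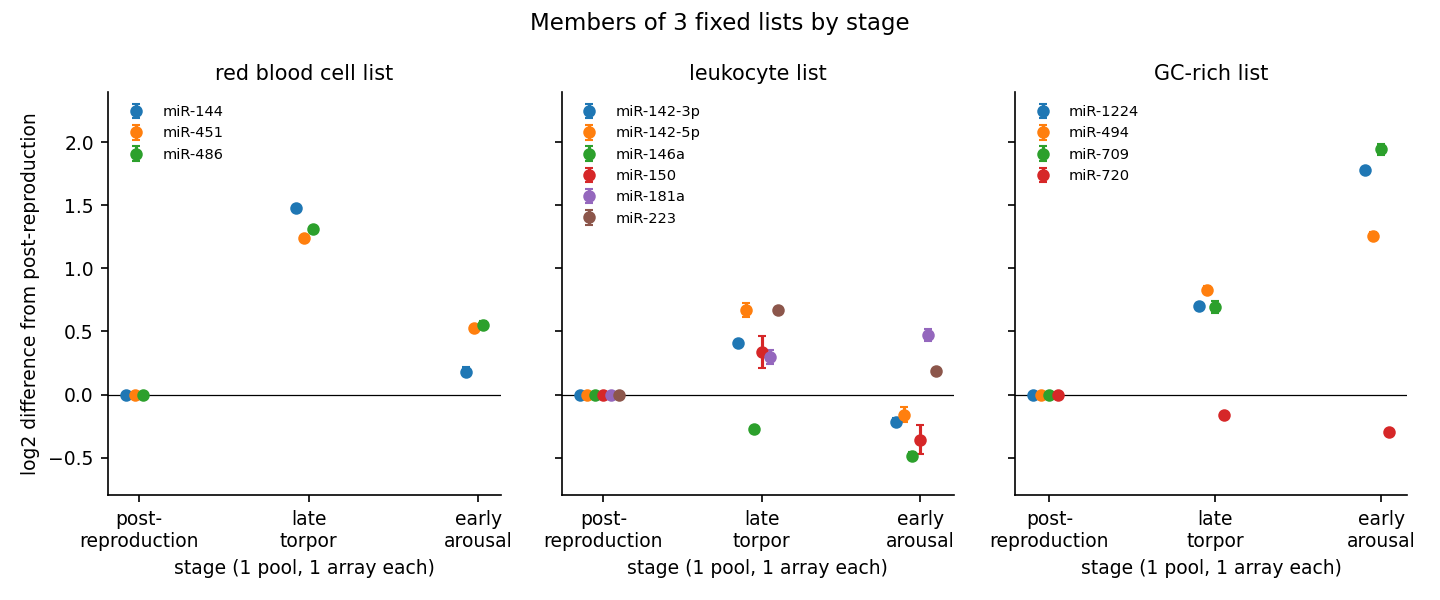
Log2 difference from post-reproduction of the measured members of the erythroid, leukocyte and GC-rich lists in each stage (1 array each), with bars for the SE from spots and post-reproduction at 0. The erythroid members lie between 1.24 and 1.48 in late torpor and between 0.18 and 0.55 in early arousal, where miR-144 lies below 0 with both all-probe scalings or without scaling, while miR-709 lies at 0.70 and 1.94.

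The third comparison set early arousal against late torpor, both within hibernation. The miRNAs past the rule were 2 higher and 2 lower in early arousal. Only measured miRNAs are counted, so entries detected on these 2 arrays but not in post-reproduction are left out. One such entry is miR-483, whose brightest probe had 30.1 intensity units in early arousal and 10.5 in late torpor (scaled log2 values of -3.54 and -5.06). miR-709 was 2.38-fold higher (95% interval from spots 2.29 to 2.47) and miR-1224 2.12-fold higher (2.06 to 2.18), and both fell short of the rule with all probes in the scaling (miR-1224 at 0.83, miR-709 just under the size required) and with normexp (0.65 for miR-709, 0.88 for miR-1224). miR-144 was 2.46-fold lower and miR-500 2.39-fold lower, with log2 differences of -1.30 ± 0.04 and -1.26 ± 0.08, but at -0.60 and -0.30 with normexp neither passed the rule. miR-34a came close at -0.98 ± 0.04, and it passed with all probes in the scaling (-1.23), with the brightest probe (-1.05) and with strict detection (-1.01). miR-144 and miR-500 rested on 20 spots on each of these arrays.

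Both lists of blood cell miRNAs were lower in early arousal. The erythroid list had a median of -0.76 (0.28th percentile), with miR-486 at -0.76 and miR-451 at -0.71. The leukocyte list had 5 of 6 members lower and a median of -0.56 (0.125th percentile), with miR-142-5p at -0.83 ± 0.06, miR-223 at -0.49 ± 0.02 and miR-181a at 0.18, which was below 0 with all probes in the scaling. The leukocyte list came inside the middle 95% with the total intensity (-0.23) and in the brighter miRNAs alone (-0.49). With all probes in the scaling, miR-142-5p (-1.08) and miR-486 (-1.01) passed the rule. The GC-rich list was higher with a median of 0.76 (100th percentile after rounding). let-7 members were lower in 9 of 9, though 4 were higher with the median scaling, 2 after quantile normalization and 5 with the unsubstituted all-probe scaling. Their median of -0.16 lay at the 19.2nd percentile, and let-7i was the lowest at -0.31. miR-122 was at -0.20 ± 0.03, miR-378 at -0.31 ± 0.03, miR-21 at -0.19 ± 0.01 and miR-200a at 0.28 ± 0.08, with miR-122 and miR-21 above 0 under the unsubstituted all-probe scaling. miR-365 was the highest hepatocyte miRNA at 0.25 and miR-148a the lowest at -0.39. miR-671-3p was at least 3.67-fold higher in early arousal and miR-540-3p at least 2.04-fold (1.72-fold with all probes in the scaling), with the bound of miR-770-3p between them, while miR-190b was at least 2.15-fold higher in late torpor (1.86-fold with the unsubstituted all-probe scaling). For miR-671-3p, miR-770-3p and miR-540-3p the bound rested on 5 spots of 1 probe, the only 1 of 4 detected in early arousal. Those probes had 31.3, 26.5 and 17.4 intensity units there, against 22.2 for the viral background entry mghv-miR-M1-2. In late torpor miR-190b had 21.7, against 26.3 for that entry.

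With all probes in the scaling, 0 miRNAs were higher past the rule and 5 were lower. The median of all measured miRNAs then lay at -0.34 in place of -0.094, and it was 0.058 with the median scaling and 0.12 with the unsubstituted all-probe scaling, which gave 2 higher and 2 lower.

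**Figure D3:**
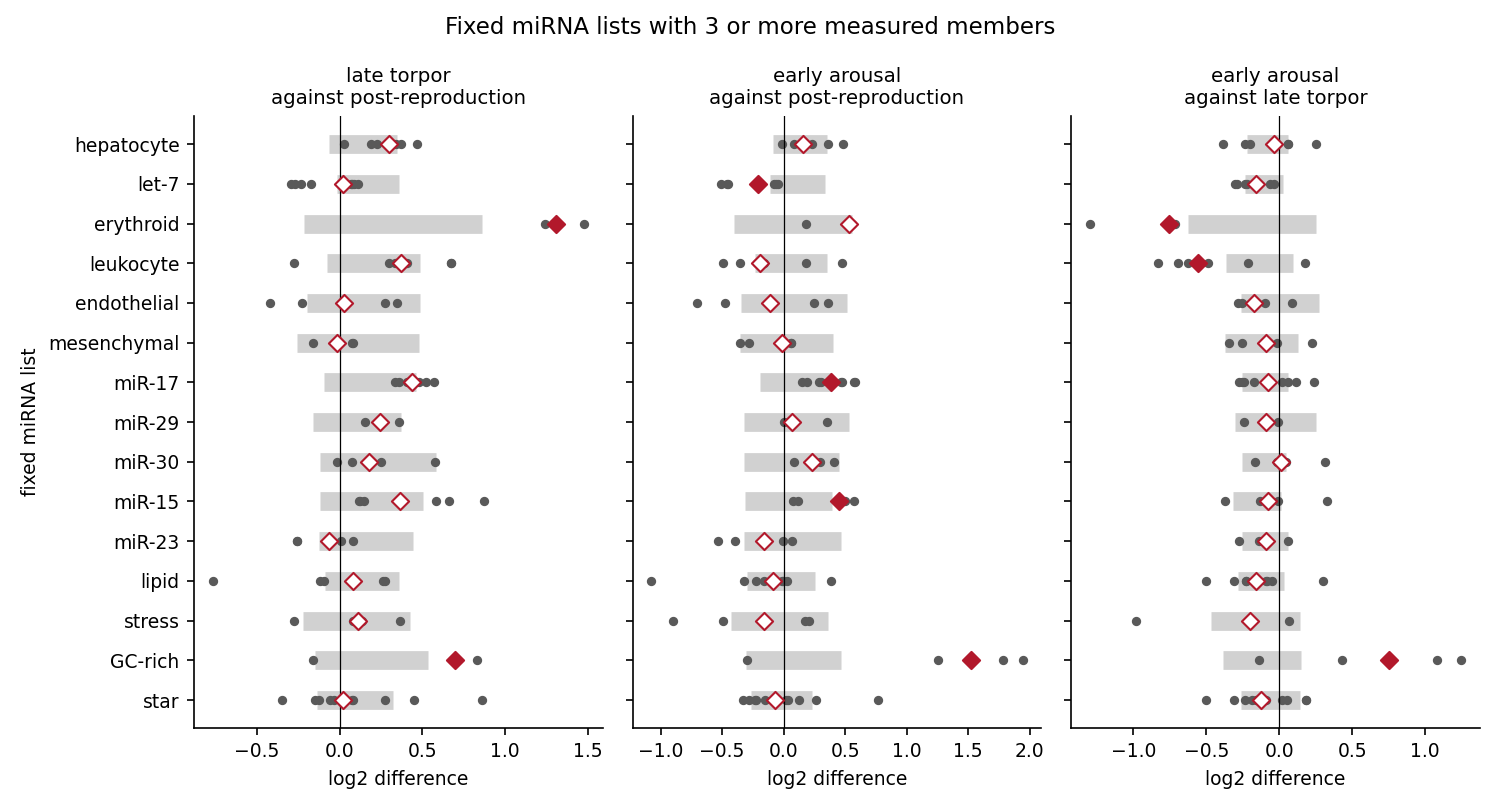
Log2 differences of the measured members (grey points) and their median (diamond) for the 15 lists with at least 3 measured members, in the 3 comparisons. Grey bars span the middle 95% of matched random lists, and a filled diamond lies outside its bar, as in 9 of 45 cases, among them the erythroid list in late torpor (1.31) and the GC-rich list in each comparison (0.70, 1.52 and 0.76).

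No miRNA passed the rule of size against post-reproduction in both late torpor and early arousal, where independent lists would share 0.089 among the higher ones. At the looser size of 1.5-fold, 5 miRNAs were higher in both (miR-1224, miR-31*, miR-452, miR-494 and miR-709) and 4 lower in both (miR-152, miR-186, miR-200b and miR-378), against 0.89 and 0.4 for independent lists. These names at the looser size were picked after their values were seen. Across miRNAs, which are not independent replicates, the 2 sets of differences had a Pearson correlation of 0.69 and a covariance of 0.119. Simulated arrays that shared the post-reproduction array and differed by spot noise alone gave a correlation of 0.47 and a covariance of 0.00113. That simulation held no spread between pools or arrays, so it does not give the value for unchanged pools. The post-reproduction pool enters both comparisons and 1 array cannot be split, so part or all of the covariance and of the shared miRNAs may come from that pool and array.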

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

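In this part, the tests of scaling for miR-144 and its partners, of more blood, of a local defect, of a raised background, of list entries detected on no array and of the miR-17 list were chosen after the result was seen. Of the 10 viral entries, which served as background, 8 were detected on none of the arrays and 2 on at least 1. mghv-miR-M1-2, a miRNA of a mouse herpesvirus, was detected on all 3 arrays, with 22.2 intensity units for its brightest probe in early arousal, 26.3 in late torpor and 26.5 in post-reproduction. It was the 1 measured member of the viral list, with log2 differences of 0.28 in late torpor against post-reproduction (-0.11 with the unsubstituted all-probe scaling), -0.10 in early arousal against post-reproduction and -0.38 in early arousal against late torpor. mghv-miR-M1-8 was detected in late torpor alone, at 9.96 for 1 of its 4 probes, whose mean deposited intensity was 1.98 in early arousal, with post-reproduction in between. No bound was given for mghv-miR-M1-8, because its brightest probe over the 3 arrays was not the detected one. No explanation was tested for them.

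The first pattern weighed was the higher level of miR-144, miR-451 and miR-486 in late torpor than in post-reproduction. The choice among the scalings and summaries run does not account for it, since the lowest of the 3 differences under any of the other scalings, corrections and summaries was 0.75. No scaling on control entries was run. By the main scaling the control entries hur_1, hur_2, hur_4 and mr_1 were higher in late torpor by 0.40 to 0.54. hur_6 was higher by 1.10, and the bright corner spots were at -0.22. More blood in the late torpor pool may account for the higher level of the 3 miRNAs, and it stays open. Blood with the same share of leukocytes in each stage would bring the leukocyte list along. That list lay at the 87.5th percentile, above the middle of random lists but inside their middle 95%. From late torpor to early arousal it was lower together with the erythroid list (medians -0.56 and -0.76), as more such blood in late torpor would give. That comparison uses the same late torpor array, so it is not separate support. In early arousal against post-reproduction the 2 lists did not move together. The erythroid median was 0.53 and the leukocyte median -0.19 (0.044 with normexp). The share of leukocytes in the blood was not measured, so the leukocyte list cannot decide the question. The 3 erythroid differences lay within 0.24 of each other here, but they ran from 0.18 to 0.55 in early arousal against post-reproduction and from -1.30 to -0.71 in early arousal against late torpor, a spread that 1 common red cell share alone would not give. miR-144 alone made that spread. miR-451 and miR-486 lay close together, at 0.53 and 0.55 and at -0.71 and -0.76, as a common share would give. The stage itself, as a biological cause in liver or in blood, was not tested and cannot be told apart from the pool and the array.

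The second pattern was the higher level of miR-709, miR-1224 and miR-494 in early arousal. A local defect of the array is argued against: 192 spots of other entries within 2 rows and columns of theirs had a median log2 difference only 0.0072 ± 0.038 (bootstrap SE) above that of spots farther away. A raised background is argued against too: the negative controls differed by 0.00216 of the gain of miR-709, the dimmest of the 3. Neither test covers other differences between the arrays. After the main scaling the bright corner spots, 1 control probe, were 2.63-fold higher in early arousal than in post-reproduction. The control entries hur_1, hur_2, hur_4, hur_6 and mr_1 were 1.17-fold to 1.32-fold higher. The cause of these was not tested. More broken RNA or cross-hybridisation in the early arousal pool stays open. The 11 unmeasured members of the same list had a median difference of 1.24 intensity units. That lay at the 100th percentile of random sets of unmeasured entries, above their middle 95%, as this cause would give. But 4 of the 11 were detected in early arousal and 0 in post-reproduction. The 7 detected on no array, a split chosen after the result was seen, lay at the 86.6th percentile. miR-720, the brightest member, was at -0.30. For a general gain of probes with short targets, 45 other miRNAs with short targets lay 0.078 ± 0.076 (bootstrap SE) in log2 above the other 87. That is below the size set beforehand for such a gain by more than 2 SE, which argues against a gain of that size in these 45. A smaller general gain stays open, since the limit set beforehand against any gain was met by less than 1 SE. The targets of the 3 miRNAs spanned 10.5 to 14.5 bases and those of the 45 up to 16.5, and a gain of the shortest targets alone was not tested. A real change of the 3 miRNAs stays open too.

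The third pattern was the higher level of the miR-17 list in both stages against post-reproduction. Whether the list differed from 0 could depend on the scaling, since its lowest median was 0.015, in early arousal with all probes. A scaling of that kind moves every miRNA of an array alike, so it decides nothing about the list's place among the others. More blood also stays open: by the main scaling all 8 members gained more in early arousal than the ratio of the red blood cell miRNAs allows, but only 4 did so under the least favourable scaling. The shared post-reproduction array and the stage itself cannot be told apart here.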

How the results depend on the processing

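No paired analysis was possible because each stage is 1 pool on 1 array. All but the floor of the bounds and the unsubstituted all-probe scaling were planned before the data were examined. The deposited series table holds the same values and changed nothing. Each of the 12 differences past the rule of size kept its direction under every alternative run on it, and 2 stayed past the rule under all of them (miR-709 and miR-1224 in early arousal against post-reproduction). The detected miRNAs per array stayed within 1.5 times under both other detection calls. Of 132 differences named but not past the rule, 9 passed it under at least 1 alternative and 65 changed sign under at least 1. miR-122 is 0 after quantile normalization by construction, being the brightest on each array. Signal over background limits the dim miRNAs: normexp, which adds 50 to each intensity, shrinks them by construction.

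In late torpor against post-reproduction, 3 higher and 0 lower became 1 lower with all probes in the scaling, with the median and without scaling, 1 higher and 6 lower with the unsubstituted all-probe scaling, 1 higher with normexp, 7 higher and 2 lower with the total intensity, 2 lower with strict detection, and 15 higher and 6 lower at 1.5-fold. In early arousal against post-reproduction, 4 higher and 1 lower became 2 and 8 with all probes, 3 and 3 without scaling and with the unsubstituted form, 2 lower after quantile normalization, 2 and 0 with normexp, 5 lower with the total intensity, 2 and 2 with strict detection, 2 and 0 in the brighter miRNAs, and 8 and 9 at 1.5-fold. In early arousal against late torpor, 2 higher and 2 lower became 0 and 5 with all probes, 0 and 0 with normexp, 1 and 0 in the brighter miRNAs, and 9 lower at 1.5-fold. In both stages against post-reproduction, 0 and 0 became 1 lower with all probes and with the unsubstituted form, 1 and 1 with the total intensity, 1 lower with strict detection, and 5 and 4 at 1.5-fold. A looser size and fewer miRNAs act by construction, and the cause was not tested for the others.

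Of the lists outside the middle 95%, let-7 in early arousal against post-reproduction came inside with normexp (-0.084) and in the brighter miRNAs (-0.20). The leukocyte list in early arousal against late torpor did so with the total intensity (-0.23) and in the brighter miRNAs (-0.49). miR-17 in early arousal against post-reproduction did so after quantile normalization (0.31) and with the brightest probe (0.32), and miR-15 with the total intensity (0.34), strict detection (0.19) and the brighter miRNAs (0.48). GC-rich in late torpor came inside in the brighter miRNAs (0.70). In late torpor, miR-17 came to lie outside with the brightest probe (0.47) and strict detection (0.20), and miR-15 with strict detection (0.35). The cause was not tested. The floor at the lowest mean of a detected probe, chosen after seeing the data, gave 5 in place of 3 bounds of at least 2-fold for entries brighter in early arousal than in late torpor. Bounds of at least 2-fold in late torpor over post-reproduction went from 2 to 1 with all probes or the median, and to 0 without scaling or with the unsubstituted form.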

Other observations

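Control entries on the arrays, which the comparisons left out, were not equally bright in the 3 stages. They were looked at after the main values were seen, and the files do not say what they detect. After the main scaling, hur_6 was 2.15-fold higher in late torpor than in post-reproduction, while hur_1, hur_2, hur_4 and mr_1 were 1.34-fold, 1.46-fold, 1.38-fold and 1.32-fold higher. In early arousal these 5 were 1.17-fold, 1.20-fold, 1.31-fold, 1.20-fold and 1.32-fold higher than in post-reproduction, in the same order. The bright corner spots had a median of 495 intensity units on the early arousal array, 154 on the late torpor array and 207 on the post-reproduction array. The dmr entries were not above background on any array.

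A total of 7 mouse miRNAs were detected on the late torpor array alone, 6 on the early arousal array alone and 1 on the post-reproduction array alone. A bound above both other arrays was given for 5 of the 6 in early arousal but for 2 of the 7 in late torpor. Each of the 5 in early arousal rested on 5 spots of 1 probe, the only 1 of 4 detected. The other, miR-874, had none because its brightest probe over the 3 arrays was not the detected one. The detected probe of miR-874 had a mean deposited intensity of 11.9 in early arousal, 2.07 in late torpor and 2.29 in post-reproduction. The 2 in late torpor were miR-133a, at least 1.40-fold over early arousal and 1.51-fold over post-reproduction, and miR-678, at least 1.01-fold and 1.09-fold. Under each other scaling that shifts whole arrays miR-133a alone kept both bounds. The other 5 in late torpor had no bound over early arousal by the main scaling. For miR-466h this came from its low mean of logs. Its mean deposited intensity was 14.2 in late torpor, -0.859 in early arousal and -1.41 in post-reproduction. The muscle list had 3 detected members in late torpor, 2 in early arousal and 0 in post-reproduction. Their signal was low. In early arousal miR-1 and miR-133b were at 10.7 intensity units, where the lowest spot well above background was at 10.1. Their bounds over post-reproduction were 1.14-fold. The viral entry mghv-miR-M1-2, a background entry, was brighter than the muscle miRNAs on each array (22.2 to 26.5). Detection at this level does not show that a muscle miRNA was present. miR-133b, a muscle miRNA, had 21.2 intensity units for its brightest probe in late torpor and 8.59, not well above background, in post-reproduction. miR-211 was the reverse case, with 38.8 intensity units in post-reproduction and 6.72, not well above background, in early arousal. In late torpor the same probe of miR-211 lay in between.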
